A study of Rattus norvegicus with 25 samples.

How the data were processed

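Faecal bacteria of Wistar rats were profiled with the HuGChip, a microarray whose probes are complementary to the bacterial 16S rRNA gene. Per the labels, the rats' diets over 12 weeks held either linseed oil or a control oil of equal energy, each with or without wheat aleurone. The groups are called PO (control oil), A+PO (the same with aleurone), LO (linseed oil) and A+LO (linseed oil with aleurone). Aleurone is the bran layer next to the starchy part of the grain, and linseed oil is rich in the plant omega-3 fatty acid alpha-linolenic acid. Per the labels' protocols, 16S genes were amplified from 10 ng of faecal DNA over 35 PCR cycles, 1 µg of product was labelled with Cy3 or Cy5, and 250 ng was hybridised, with samples of both dyes on an array. The series has 25 samples on 13 arrays: 6 PO and 6 LO samples in Cy3, 6 A+PO and 7 A+LO samples in Cy5.

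The deposited values are spot intensities on a linear scale, written per the file headers by Agilent Feature Extraction 10.5.1.1 with a dye-coupled protocol. The mean spot signal and the median local background were used as deposited; both are pixel intensities without normalisation. The deposited background-subtracted intensities and the deposited processed intensities, which Feature Extraction adjusts between the dyes, were used only as alternatives. Each array has 14080 spots, of which 13323 belong to 4441 probes of 25 bases with 3 spots each. Another 18 probes, whose names begin with MCR, have 10 spots each and were left out of the comparisons. One Cy3 channel has no listed sample and was not used, so sample A+LO 11 stands alone on its array. For 4 A+LO samples the labels and the columns give different numbers. They are named here by the LO sample on the same array.

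The probe names begin with 1 of 66 numbers, and probes sharing a number are called a probe set here. That such a set stands for 1 bacterial family is an inference from the names. No taxon is paired with the sets, so no set is given a name, and the 12 lists of bacterial families and the 20 families chosen before the data were examined could not be computed.

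Each dye was treated as a single channel. Background was corrected by the normexp method with an offset of 50, values were put on the log2 scale, and the 75th percentile of the channel over the 405 probes above background in all 25 samples was subtracted. Spots that Feature Extraction marks as outliers were left out, unless all spots of a probe were marked. A probe was counted as detected where over 0.5 of its remaining spots were well above background by the Feature Extraction test. The comparisons used 1153 probes detected in at least 6 of the 25 samples. A set's value is the mean over its kept probes, for the 53 sets with at least 3. Precision is limited by the number of arrays.

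Differences were tested with limma 3.58.1 in R 4.3.3, with 4 group means fitted over all 25 samples, the array as a random block (correlation 0.760 between samples of an array for probes and 0.692 for sets) and Benjamini-Hochberg adjustment within each comparison. An adjusted p under 0.05 passed. Because A+LO 11 has no partner on its array, fitted differences can depart slightly from differences of group means. The comparisons were linseed against control oil without aleurone, with aleurone and averaged over both, aleurone against none with each oil, and the interaction, (A+LO minus LO) minus (A+PO minus PO). Aleurone samples were all Cy5 and the others all Cy3, so aleurone and dye cannot be told apart. The 6 arrays of the control-oil groups lie on one slide and the 7 arrays of the linseed groups on another, scanned separately, so oil and slide cannot be told apart. An additive effect of dye or slide cancels in the interaction, and an effect of the dye that differs between slides does not.

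Composition was compared by a pseudo-F (PERMANOVA) on Bray-Curtis dissimilarities of the linear values over kept probes, and for the interaction on Euclidean distances of the within-array log2 differences of the 12 arrays with 2 samples. The number of detected probes and the Shannon index (natural logarithm) over kept probes were compared by differences of means. All of these used exact permutation tests over every split, two-sided for the differences of means. The pseudo-F was checked against vegan 2.7.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

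Named items follow a rule fixed in advance: the probes and sets past the test with the largest differences, with probes required to be detected in every sample of a compared group. At most 2 higher and 2 lower are named per comparison because the IDs carry no taxon. This limit was fixed in advance for probes only. It was applied to the sets too, in place of a larger limit fixed for named families. Where fewer than 4 sets passed, sets with the smallest p are given as not past the test. For each named item the number of samples in its direction is given: LO or A+LO samples on that side of the mean of the control-oil group, arrays with that sign of the aleurone difference, or linseed arrays on that side of the control-oil arrays' mean. Differences are also given relative to the median difference of all kept probes or sets.

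The numbers of PO and A+PO samples coincide with the arrays. Their deviations from the group means, correlated over probes, gave r from 0.867 to 0.940 in the 6 pairs. Number and array are the same in these pairs, so this cannot show a pairing by number apart from the array. The array block carries both. For other groups, a shared number does not mark a shared array.

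The procedure was tested on simulated data with known changes built on the real spread. Of 100 probes changed by 2 on the log2 scale, it recovered 8 for LO against PO, 7 for A+LO against A+PO, 13 for the averaged oils, 60 for A+PO against PO, 63 for A+LO against LO and 22 for the interaction. Of 100 probes changed by 4, it recovered 55, 49, 55, 96, 99 and 85 in the same order, each step being run on 1153 probes. Of all probes called in these simulations, between 1.45% and 8.7% per comparison had not been changed. The simulated noise was drawn separately for each probe, while real probes of different sets varied together over samples (median r 0.326). Shifts shared by many probes were thus not simulated, and these rates need not hold for the real data.

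Alternatives tried were the background-subtracted and the processed signal, quantile scaling over all samples or within each dye, the channel median over all probes, loess within arrays with Aquantile scaling between arrays (without A+LO 11), no filter or a stricter filter on dim probes, outlying spots kept, other detection rules and distances, other summaries of sets, a fixed or no array block, a replicate block, the compared groups alone, and leaving out each sample. Chosen after seeing the data were the channel median over kept probes and leaving out the brightest and the dimmest array. Regrouped samples were refitted with the array correlation held at its value in the real grouping.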

Results

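The 25 faecal samples gave a signal on a part of the HuGChip. Of 4441 probes, 2143 were above background in at least 1 sample, 405 in all 25 samples and 2298 in none. The number of detected probes per sample ran from 576 to 1534 with a median of 970, or 13.0% to 34.5% of the probes. The median raw intensity of a sample ran from 59.1 to 684 with a median of 88.8, beside local backgrounds of 39 to 90.

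A few probe sets had most of their probes detected. Averaged over samples, 79.2% of the 21 probes of set b6967, 73.4% of the 137 probes of set b6995, 63.7% of the 165 probes of set b6955 and 54.8% of the 324 probes of set b6959 were above background. Set b6967 had 81.7% of its probes detected in PO, 82.5% in A+PO, 77.0% in LO and 76.2% in A+LO. For set b6983 the shares were 57.1%, 58.3%, 47.2% and 38.8% in the same order, and for set b6992 they were 55.3%, 53.3%, 42.7% and 31.4%. These shares of single sets were not tested. Of the 66 sets, 64 had at least 1 kept probe.

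The number of detected probes was 1112.5 ± 239 (SD, n = 6) in PO, 1103.5 ± 268 (SD, n = 6) in A+PO, 948 ± 134 (SD, n = 6) in LO and 836 ± 127 (SD, n = 7) in A+LO. The Shannon index of the signal was 6.13 ± 0.207 in PO, 5.85 ± 0.220 in A+PO, 5.90 ± 0.332 in LO and 5.37 ± 0.597 in A+LO, with the same n.

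**Figure D1:**
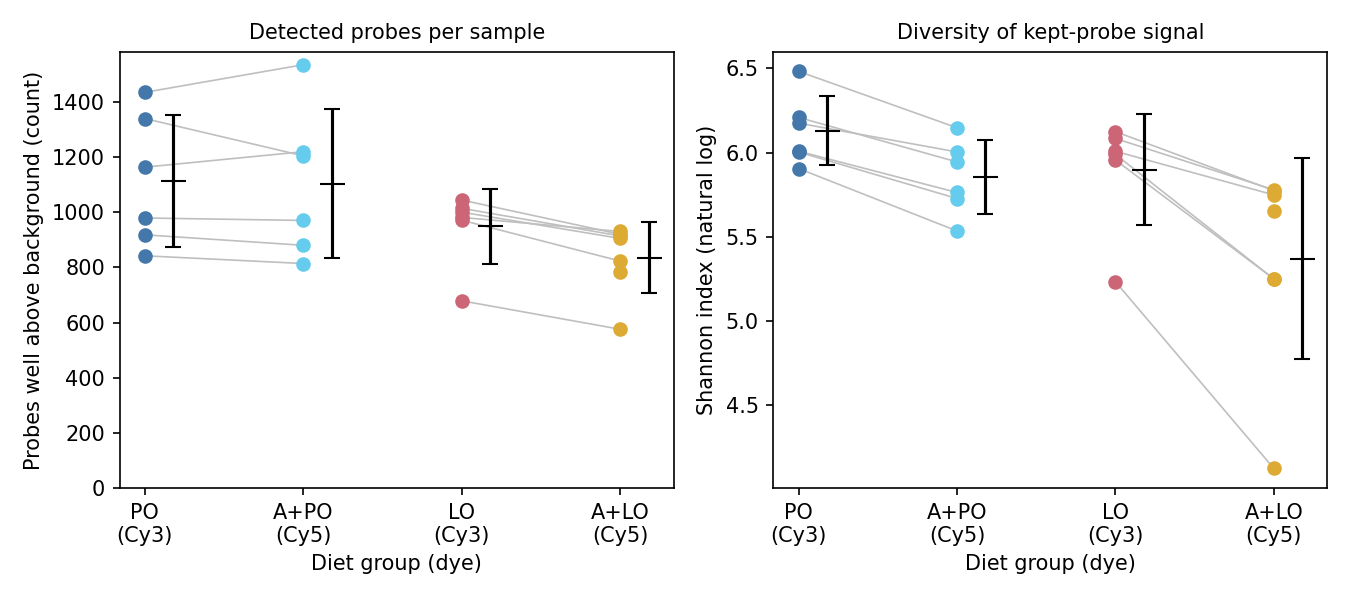
Number of probes above background (left, count) and Shannon index of the kept-probe signal (right, natural logarithm) for each sample by diet group, with the group mean and SD in black and grey lines joining samples of an array. The A+LO samples run from 576 to 930 detected probes and the A+PO samples from 814 to 1534.

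The first comparison asks whether linseed oil changed the faecal bacteria in rats without aleurone. No probe and no set passed the test. The sets with the smallest p were b7009, with a log2 difference of -2.29 (SE 0.984, -1.19 relative to the median set, below the PO mean in 5 of 6 LO samples), and b6962, with -2.19 (SE 0.965, -1.09 relative to the median set, 6 of 6 samples). Without the array of PO 1 and A+PO 1 the difference of b7009 was -1.35, and without PO 1 alone -1.99. Without LO 4 that of b6962 was -1.54. Neither set passed under any of the 7 other signal and scaling choices, where b7009 ran from -3.59 to -0.39 and b6962 from -2.65 to -0.29 (limma with Benjamini-Hochberg adjusted p from 0.0611 to 0.721 and from 0.0611 to 0.790). Set b6962 stood at -2.60 ± 1.24 in PO and -4.77 ± 2.15 in LO (log2, SD, n = 6 each). In limma, 0 of 1153 probes and 0 of 53 sets passed after Benjamini-Hochberg adjustment, with smallest adjusted p of 0.756 and 0.501, and 26 probes and 2 sets had an unadjusted p under 0.05, all lower in LO. The median probe differed by -1.10, but by 0.83 with the median of the kept probes and -0.02 with quantile scaling within each dye. Composition gave a pseudo-F of 0.981 (exact permutation p = 0.465, 8.93% of the variation). Detected probes differed by -164 (exact permutation p = 0.180) and the Shannon index by -0.231 (exact permutation p = 0.177). Single samples weigh on both: without PO 1 the detected probes differed by -100 and without LO 4 by -110.5, and the Shannon index by -0.0981 without LO 4. Detection at 3 background SD turned the difference in detected probes to 168.8 (exact permutation p = 0.764), and quantile scaling over all samples turned that in the Shannon index to 0.00825 (exact permutation p = 0.387). In data simulated without shifts shared between probes, this comparison recovered 55 of 100 probes changed by 4 on the log2 scale and 8 of 100 changed by 2. Most simulated differences of the smaller size were missed, so the absence of calls does not show that such differences are absent.

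With aleurone in both diets, linseed oil went with fewer detected probes. The mean number differed by -268 between A+LO and A+PO (exact permutation p = 0.0326, n = 7 and 6, not adjusted for the other single measures). The A+LO channels also had lower signal at background level. Their median raw signal ran from 59.1 to 69.3, beside 73.0 to 240 in A+PO, and their negative controls from 52.5 to 61.6, beside 63.3 to 148. The bright end was not lower throughout. The 95th percentile ran from 2673 to 330578, beside 152852 to 582458, and the highest spot from 521652 to 1331340, beside 547914 to 1016610. Whether the lower background-level signal bears on the count was not tested, and oil and slide cannot be told apart. No probe and no set passed the test. The sets with the smallest p were b6948 with a log2 difference of 2.54 (SE 0.987, 1.46 relative to the median set, above the A+PO mean in 7 of 7 A+LO samples) and b6945 with 2.38 (SE 1.02, 1.30 relative to the median set, 7 of 7 samples). Both sets lay mostly at background: over kept probes and samples, b6948 was above background in 22.2% of cases in A+PO and 11.9% in A+LO, and b6945 in 27.8% and 9.52%. Their log2 differences are therefore differences of background-level signal after scaling. Scaling on the median of all probes turned both, to -0.24 and -0.40, and the processed signal turned b6945 to -0.46. In limma, 0 of 1153 probes and 0 of 53 sets passed after Benjamini-Hochberg adjustment (smallest adjusted p 0.567 and 0.417), and 87 probes, 69 of them higher, and 4 sets, all higher, had an unadjusted p under 0.05. The median probe differed by 0.68. This direction rests on the scaling: it was -0.66 with the background-subtracted signal, -1.19 with the processed signal, -0.24 with loess, -2.10 with the median of all probes and 1.09 with the median of the kept probes. In limma with Benjamini-Hochberg adjustment 30 sets passed, all lower, with the median of all probes, 23, all higher, with the median of the kept probes and 47, all higher, without the filter on dim probes, while the processed signal and loess each gave 1 lower set. Composition gave a pseudo-F of 1.56 (exact permutation p = 0.159, 12.4% of the variation), and the Shannon index differed by -0.485 (exact permutation p = 0.0519). Without the array of PO 1 and A+PO 1 the difference in detected probes was -182 (exact permutation p = 0.0833). It was also not past the test without A+PO 2 or 3, A+LO 9 or 11, or the A+LO sample on the array of LO 4 or of LO 6 (exact permutation p from 0.0519 to 0.0779). The Shannon difference was -0.277 without the A+LO sample on the array of LO 4 (exact permutation p = 0.0823). Scaling on the median of all probes raised the pseudo-F to 3.12 (exact permutation p = 0.00408).

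Averaged over both aleurone states, no probe or set passed between the oils. Set b6962 had a log2 difference of -1.90 (SE 0.875, -1.95 relative to the median set, lower in 12 of 13 linseed samples) and set b7009 one of -1.57 (SE 0.893, -1.63 relative to the median set, 9 of 13 samples). The difference of b7009 rests largely on the array of PO 1 and A+PO 1, without which it was -0.61 (limma with Benjamini-Hochberg adjusted p = 0.814). With all arrays both sets kept a negative difference under all 7 other signal and scaling choices. Set b6962 passed under 3 of them and b7009 under 2, with adjusted p (limma, Benjamini-Hochberg) from 0.0229 to 0.376 for b6962 and from 0.0229 to 0.626 for b7009. In limma, 0 of 1153 probes and 0 of 53 sets passed after Benjamini-Hochberg adjustment (smallest adjusted p 0.998 and 0.976), with 24 probes and 1 set at an unadjusted p under 0.05. Every linseed sample was on one slide and every control-oil sample on another, so no oil difference can be told apart from a slide difference.

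Probe b6965_3_2 (CCCCGTCCCGCCCCCTGAACCGCCG), chosen after its values were seen, was the only probe past the test between the oils when the arrays were scaled by loess. After loess within arrays it stood at 10.45 ± 1.00 in PO, 9.89 ± 0.98 in A+PO, 13.70 ± 1.01 in LO and 13.11 ± 1.05 in A+LO (log2, SD, n = 6 each). The difference was 3.25 (SE 0.498, limma with Benjamini-Hochberg adjusted p = 0.00148) without aleurone and 3.23 (SE 0.498, adjusted p = 0.00166) with it. Under the 75th-percentile scaling the differences were 1.88 (adjusted p = 0.756) and 3.26 (adjusted p = 0.567), and under the median of all probes 1.93 (adjusted p = 0.432) and 0.48 (adjusted p = 0.608), by limma with Benjamini-Hochberg adjustment. Loess with Aquantile scaling adjusts both channels of an array together, so the differences with and without aleurone are not separate evidence. The probe was above background in all 25 samples, and slide and oil cannot be told apart for it either.

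**Figure D2:**
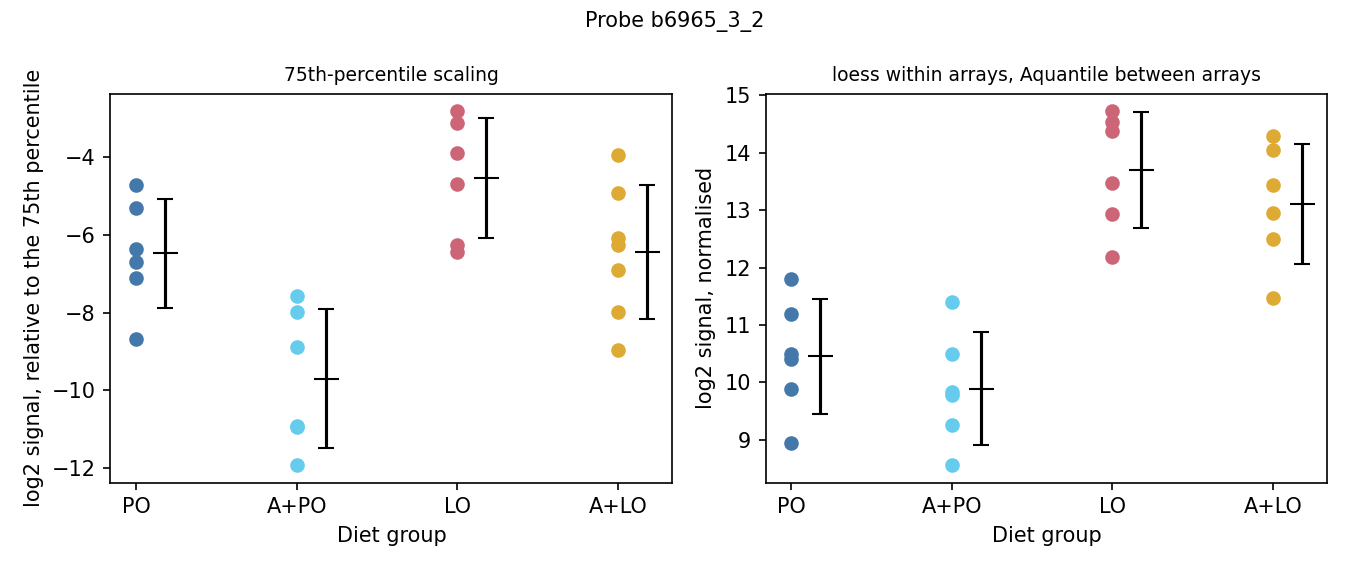
log2 signal of probe b6965_3_2 for each sample by diet group, with the 75th-percentile scaling (left) and with loess and Aquantile scaling (right), and the group mean and SD in black. On the right the LO samples run from 12.18 to 14.72 and the PO samples from 8.94 to 11.81.

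Aleurone with control oil came with lower signal on most probes when set against the brightest ones. Of 1153 probes, 762 were lower in A+PO than in PO and 0 were higher, and 49 of 53 sets were lower. Probes b7008_5_14 (GAGGTTAAGGGCGGCGAGCGGCGGA) and b7008_5_12 (GATGTTAAGGGCGGCGAGCGGCGGA) had log2 differences of -3.96 (SE 0.651, limma with Benjamini-Hochberg adjusted p = 0.000212) and -3.76 (SE 0.612, adjusted p = 0.000212), each lower in 6 of 6 arrays, and -1.98 and -1.78 relative to the median probe. Set b6995 had -2.78 (SE 0.554, adjusted p = 0.000486) and set b6939 had -2.69 (SE 0.574, adjusted p = 0.000717) by limma with Benjamini-Hochberg adjustment, each in 6 of 6 arrays, and -0.76 and -0.67 relative to the median set. The sequences of the b7008 probes differ in a single base, so they need not be separate evidence. The median difference was -1.98 over probes and -2.02 over sets, and 804 probes had an unadjusted p under 0.05. Of the 762 probes, 373 were not above background in every sample of either group. Scaling on the median of the kept probes turned the picture round, with 316 probes higher and 1 lower, b6995 at 0.06 and b6939 at 0.15, while both b7008 probes kept a negative difference under all 7 other signal and scaling choices. Probe b7008_5_14 passed under 6 of them and b7008_5_12 under 5 (limma with Benjamini-Hochberg adjusted p up to 0.203 and 0.552), with only -0.78 and -0.62 under quantile scaling over all samples. Sets b6995 and b6939 passed under 5 of the 7 each. Without the array block 0 probes and 0 sets passed in limma after Benjamini-Hochberg adjustment (209 and 19 at an unadjusted p under 0.05). Aleurone and dye cannot be told apart in these values.

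Aleurone with linseed oil came with lower signal on 47 probes and higher signal on 10, and neither number was stable. No probe passed with only the groups compared, without the array block or with a replicate block over the 2 shared numbers (0 of 1153 each in limma after Benjamini-Hochberg adjustment, with 116, 38 and 17 at an unadjusted p under 0.05). Of 64 groupings with samples exchanged within arrays, 5 gave 57 or more probes, so chance is not excluded. Probes b6955_4_5 (TTGTGTCGTGAGATGTTGGGTTAAG) and b6955_4_1 (TCGTGTCGTGAGATGTTGGGTTAAG) were higher in A+LO than in LO by 2.12 (SE 0.553, adjusted p = 0.0367) and 2.10 (SE 0.532, adjusted p = 0.0297), each in 6 of 6 arrays, by limma with Benjamini-Hochberg adjustment. Their sequences differ in a single base, so they need not be separate evidence. Probe b6955_4_5 stood at -0.01 ± 0.16 in LO (SD, n = 6) and 1.94 ± 2.29 in A+LO (SD, n = 7). In PO it was -0.02 ± 0.22 and in A+PO 0.24 ± 0.21 (SD, n = 6 each), so its wide spread was in A+LO alone. Probes b6984_5_2 (GTGCGCGGAAGGCAGGCGGAACTCG) and b6973_5_4 (GAAGAAGTGCATCGGAAACCGGGCG) had log2 differences of -3.15 (SE 0.556, adjusted p = 0.00300) and -3.11 (SE 0.602, adjusted p = 0.00432), each lower in 6 of 6 arrays. Relative to the median probe, at -0.24, these 4 probes differed by 2.36, 2.34, -2.91 and -2.87, and all 4 kept their direction under the 7 other signal and scaling choices, where the b6955_4 probes passed under 6 each and the other 2 under 5 each. Their sizes moved much: b6955_4_5 ran from 0.70 to 3.45, b6955_4_1 from 0.68 to 3.43, b6984_5_2 from -4.57 to -1.36 and b6973_5_4 from -4.57 to -1.04.

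In all, 57 of 1153 probes passed in that comparison, and 303 had an unadjusted p under 0.05. No set passed in limma after Benjamini-Hochberg adjustment (0 of 53, with 2 at an unadjusted p under 0.05). That absence rests on the scaling, since 23 to 51 sets passed under each of the 7 other signal and scaling choices, all or nearly all lower in 6 of them and 46, all higher, with the median of the kept probes. Set b6985 had a log2 difference of 1.12 (SE 0.493, adjusted p = 0.739, positive in 4 of 6 arrays) and -0.29 under the median of all probes. Without the A+LO sample on the array of LO 4 it was 0.51, so it rests largely on that sample. It passed as higher under 2 of the 7 other choices (limma with Benjamini-Hochberg adjusted p from 2.47e-05 to 0.993). Set b6948 had 1.04 (SE 0.562, adjusted p = 0.930, 5 of 6 arrays), was above background in 47.2% of cases in LO and 11.9% in A+LO, and took the other sign under 5 of the 7 other signal and scaling choices. It passed under 3 of them in opposite directions, with 2.39 under the median of the kept probes, 0.16 under loess and -0.64 under quantile scaling within each dye (limma with Benjamini-Hochberg adjusted p = 2.30e-05, 0.0198 and 3.06e-06). It was 0.40 without the A+LO sample on the array of LO 4.

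Set b6995 had a log2 difference of -1.39 between A+LO and LO (SE 0.548, limma with Benjamini-Hochberg adjusted p = 0.739, 5 of 6 arrays). It passed as lower under 5 of the 7 other choices, with values from -2.78 to 0.04 and adjusted p from 7.29e-10 to 0.908. Set b6962 had -0.97 (SE 0.539, adjusted p = 0.930, 5 of 6 arrays). It passed as lower under 6 of the 7, with values from -2.40 to 0.38 and adjusted p from 3.91e-08 to 0.401. Without LO 4 both passed as lower, with -1.98 and -1.63 (limma with Benjamini-Hochberg adjusted p = 2.80e-06 and 1.51e-05), and without A+LO 9 b6962 was -0.52. The higher probes b6955_4_5 and b6955_4_1 fell to 1.34 and 1.39 without the A+LO sample on the array of LO 4. No higher probe passed, those of b6955_4 included, in 7 of 13 refits without 1 sample (LO 3, 6, 8, 9 or 11, A+LO 9, or the A+LO sample on the array of LO 6), with a fixed array block (0 higher, 11 lower), without the filter on dim probes (0 higher, 5 lower) or with the median of all probes (0 higher, 665 lower). Without LO 4, 504 probes passed (38 higher, 466 lower), and without LO 6 it was 4, all lower. Dye and aleurone cannot be told apart here either, and the median of the kept probes gave 480 higher and 5 lower probes.

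The interaction, which the series title names, asks whether the aleurone difference was another one with linseed oil than with control oil. Of 1153 probes, 325 had a more positive aleurone difference with linseed oil and 0 a more negative one, and 33 of 53 sets did so. Most of this lay on dim probes: 273 of the 325 were not above background in every sample of any diet group. Probe b7008_5_12 had an interaction of 3.81 (SE 0.861, limma with Benjamini-Hochberg adjusted p = 0.0110) and b7008_5_11 (GCGTTCATGGGCGGCGAGCGGCGGA) one of 3.77 (SE 0.862, adjusted p = 0.0110), each in 6 of 6 linseed arrays, and 2.31 and 2.26 relative to the median probe. Set b6948 had 3.24 (SE 0.799, adjusted p = 0.0110) and set b6945 had 3.02 (SE 0.825, adjusted p = 0.0119) by limma with Benjamini-Hochberg adjustment, each in 6 of 6 linseed arrays, and 1.28 and 1.06 relative to the median set. For set b6948 the log2 values were -9.74 ± 1.37 in PO, -11.93 ± 0.88 in A+PO, -10.22 ± 2.11 in LO and -9.40 ± 2.25 in A+LO (SD, n = 6, 6, 6 and 7). Sets b6948 and b6945 were above background in only 11.9% and 9.52% of cases in A+LO and 22.2% and 27.8% in A+PO, so their values compare background-level signals after scaling. Set b6948 also passed under 2 of the 7 other signal and scaling choices, with adjusted p by limma with Benjamini-Hochberg from 0.00172 to 0.975. Its interaction was smaller under all of them, from 0.04 to 2.63, and the smallest adjusted p, with loess, went with 0.41.

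Composition and the number of detected probes gave an aleurone difference that was not alike with both oils. Neither is separate evidence for the more positive probes. The pseudo-F uses the same scaled log2 differences, and the number of detected probes fell more with linseed oil, which is the opposite direction. The pseudo-F of the within-array differences was 4.28 (exact permutation p = 0.00216, 30.0% of the variation). It was not past the test with the background-subtracted signal (2.13, exact permutation p = 0.0541), the processed signal (1.37, exact permutation p = 0.177), quantile scaling over all samples (1.05, exact permutation p = 0.271) or within each dye (1.04, exact permutation p = 0.325), or with only probes above background in every sample of a group (2.15, exact permutation p = 0.0541). Detected probes differed within arrays by -103.5 ± 32.4 with linseed oil and -9.0 ± 81.5 with control oil (SD, n = 6 arrays each), an interaction of -94.5 (exact permutation p = 0.0260). Without the array of LO 11 it was -85.6 and not past the test (exact permutation p = 0.0563). The Shannon index differed within arrays by -0.578 ± 0.332 and -0.277 ± 0.0701, an interaction of -0.301 (exact permutation p = 0.0519), and -0.195 without the array of LO 4. The median interaction was 1.51 over probes and 1.96 over sets, and 444 probes had an unadjusted p under 0.05. With only probes above background in every sample of a group, 5 probes and 0 sets passed in limma after Benjamini-Hochberg adjustment (125 and 11 at an unadjusted p under 0.05). Under other scalings the median over probes ran down to -1.31, where 177 probes were lower and 1 higher. Probes b7008_5_12 and b7008_5_11 and set b6945 passed under none of the 7 other signal and scaling choices (adjusted p by limma with Benjamini-Hochberg from 0.0855 to 0.929, from 0.149 to 0.982 and from 0.0796 to 0.975). None of them turned negative, but their values went down to 0.998, 0.199 and 0.0398. Without PO 1 no probe passed in limma after Benjamini-Hochberg adjustment (0 of 1153, with 355 at an unadjusted p under 0.05). Sets b6948 and b6945 passed in 23 of 25 refits without 1 sample, but not without PO 1 or without A+LO 1. Without the array block 0 probes and 0 sets passed in limma after Benjamini-Hochberg adjustment (16 and 1 at an unadjusted p under 0.05).

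**Figure D3:**
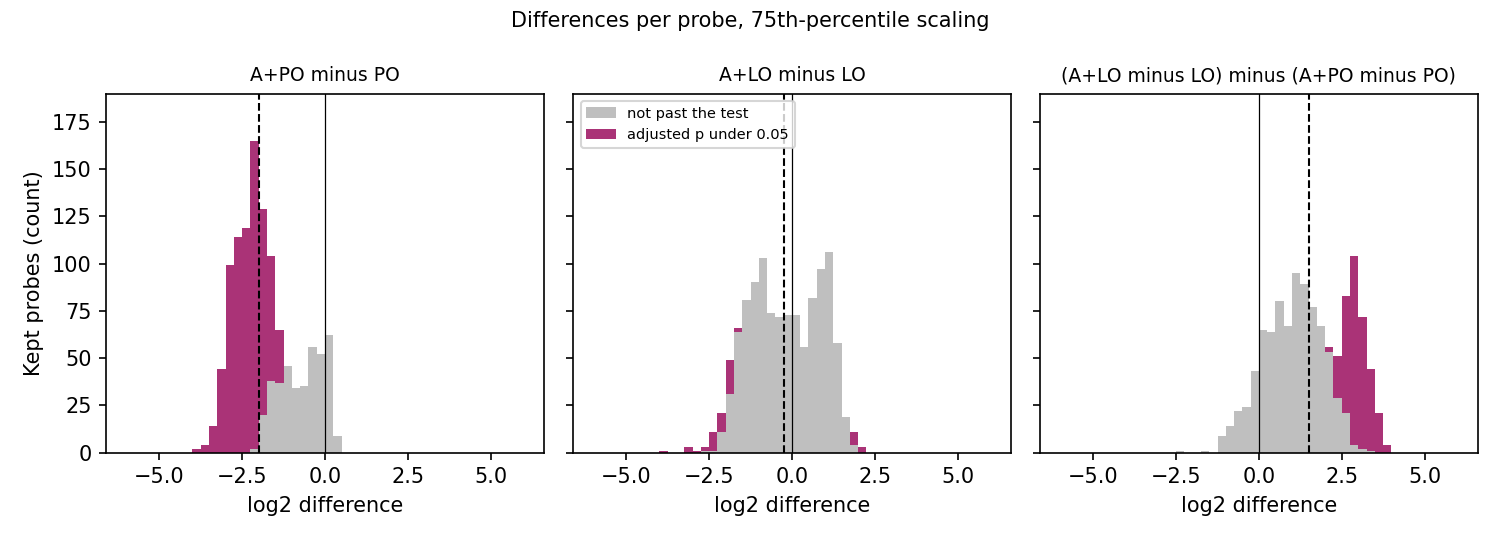
Histograms of the log2 differences of the 1153 kept probes (horizontal axis, log2; vertical axis, number of probes) for A+PO minus PO, A+LO minus LO and the interaction with the 75th-percentile scaling, probes past the test in purple and the median as a dashed line. The medians lie at -1.98, -0.24 and 1.51 here and move with the scaling, down to -1.31 for the interaction with the median of all probes.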

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

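Chosen after the results were seen were the tests on array partners and on shared numbers, both tests on the interaction, and all counts of regrouped samples. The criteria for the tests of dye leakage and of probe b6965_3_2 were set beforehand, but that probe itself had been chosen after its values were seen. Outlying values were sought in 84 tests, each of 1 measure or named item within 1 diet group, and 20 were found. All of them fell on PO 1, A+PO 1, LO 4, the A+LO sample on its array, or A+LO 9. Chance alone gives about 1 in 20 tests. That rate is no yardstick here, because the tests share samples and arrays and many items were picked from these data.

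LO 4 and the A+LO sample on its array stood low in detected probes and the Shannon index. LO 4 had 679 detected probes beside 971 to 1044 in the other LO samples, a Shannon index of 5.23 beside 5.96 to 6.12, and a median log2 value of -10.44 beside -6.87 to -5.24. Its partner had 576 detected probes beside 782 to 930 and a Shannon index of 4.12 beside 5.25 to 5.78. The 95th percentile of that partner's raw signal was 2673, beside 45898 to 330578 in the other A+LO samples. Its median log2 value after scaling was not low, at -6.45 beside -10.08 to -6.08. Probe b6955_4_5 was at 0.30 and b6955_4_1 at 0.43 in LO 4, above the other LO samples, and set b6985 was at 1.23 in its partner.

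PO 1 and A+PO 1, on another array, stood high. The median raw intensity was 684 in PO 1 beside 85.8 to 129 in the other PO samples, and 240.4 in A+PO 1 beside 73.0 to 89.1. Negative control spots had a median of 500.4 in PO 1 and 148 in A+PO 1, and 48.2% of the spots of A+PO 1 were marked as outliers by Feature Extraction beside 16.8% to 26.5%. Set b7009 was at -0.74 in PO 1 and -1.44 in A+PO 1, and set b6945 at -6.26 and -9.31, above the others of their groups. Probe b6973_5_4 was at -8.19 in PO 1 and -10.34 in A+PO 1, below the others. Set b6962 was at -9.77 in A+LO 9, below the other A+LO samples.

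Samples on one array departed from their group means together, with r from 0.670 to 0.944 in 12 pairs. Hybridisation or washing shared by the array may account for this. The 6 pairs of the linseed slide, whose numbers differ by the labels and by the columns alike, had a median r of 0.825 (0.670 to 0.944). The 2 of them with settled numbers had a median r of 0.850. Samples with the same number on different arrays were not alike, as 10 such pairs had a median r of -0.0482 (range -0.340 to 0.377). Only LO 9 with A+LO 9 (-0.340) and LO 11 with A+LO 11 (0.00382) lie on the same slide. The others set a control-oil sample against a linseed sample, and some samples recur. PO and A+PO samples with the same number always share an array, so a likeness by number cannot be tested for them. Leakage between the dyes stays open, because spots bright in Cy5 were seldom dim in Cy3 (first percentile of the ratio, median over arrays 0.517). That ratio was 0.238 (0.189 to 0.637) on the control-oil slide and 0.766 (0.307 to 1.47) on the linseed slide. For spots bright in Cy3 it was 0.166, with 0.347 (0.225 to 0.522) on the control-oil slide and 0.0385 (0.0127 to 0.107) on the linseed slide. Cy3 light reaching the Cy5 channel was thus small on the linseed slide, and the other ratios set only loose upper bounds. A likeness of the rats or their diets within an array was not tested.

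The aleurone difference was more positive with linseed oil on 325 probes and in 33 sets. The pseudo-F was 4.28 on the same scaled differences, and detected probes went the other way, with -94.5. Each is from a test of the difference between the oils' arrays. Of the 325 probes, 273 were not above background in every sample of any group. Much of this shift lay on background-level signal. The median interaction was 2.71 without the filter on dim probes, where 2298 of 4441 probes were above background in no sample. It was 0.97 over probes above background in every sample of a group. Whether scaling on the brightest probes produces the whole shift stays open. The median interaction of 1.51 was -1.31 with the median of all probes, but that choice, quantile scaling and loess all centre the channels, so where the median comes to lie decides nothing about the cause. A diet interaction on these probes stays open: after loess they lay 0.357 (log2) above the other kept probes, but they had been picked for being high. An effect of the dye that differs between the slides cannot be told apart from it by this design.

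Probe b6965_3_2 was brighter with linseed oil after loess in both dyes (3.25 and 3.23), but by 0.48 (limma with Benjamini-Hochberg adjusted p = 0.608) with aleurone under the median of all probes. Loess with Aquantile scaling adjusts both channels of an array together, and samples on an array departed together. The values of both dyes are therefore not separate evidence. A local spot defect is argued against, because each of its 3 spots gave a difference between 3.14 and 3.30 (log2, after loess). A change of the whole set b6965 is argued against, because its 34 other kept probes had a median difference of 0.0838, with 19 of them higher. A target shared with overlapping probes could not be examined, as 0 probes share 18 or more bases with it. A bacterium favoured by linseed oil may carry the matching sequence, but slide and oil cannot be told apart, and that was not tested.

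Regrouped samples were refitted to see how often chance gives as many calls, which leaves dye and slide effects untouched. For LO against PO, A+LO against A+PO and the averaged oils, limma gave 0 probes and 0 sets (26, 87 and 24 probes and 2, 4 and 1 sets at an unadjusted p under 0.05), so that 100 of 100 regroupings gave as many by construction, which tests nothing, and the highest of the others were 0, 108 and 4 probes and 0, 2 and 27 sets. For A+PO against PO, with samples swapped within arrays, only the real grouping of 32 gave 762 probes (highest other 7) and 49 sets (highest other 33). No share under 1 in 32 can be reached there, so chance is unlikely for these counts but not excluded. For A+LO against LO, 5 of 64 gave 57 or more probes (highest other 472), so chance is not excluded for the probes. For its sets, 0 were observed (2 at an unadjusted p under 0.05 in limma), so 64 of 64 gave as many by construction (highest other 37). The samples of the array of LO 4 exchanged gave 460 probes and those of the arrays of LO 3 and LO 4 gave 472, several times the real count, which points to a structure of the samples; what it is was not tested. For the interaction, 100 of 924 possible groupings were tried, the real one included. Only the real one gave 325 probes (highest other 167) and 33 sets (highest other 29), so chance is unlikely for these counts but not excluded. Both counts fell to 0 without PO 1.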

How the results depend on the processing

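Chosen after seeing the data were the median over kept probes and leaving out the brightest and the dimmest array; every other alternative was chosen before the data were examined. Where a result changed, the cause was not tested unless stated. Single probes and sets named in this part were chosen after their values were seen. Counts are of probes or sets past adjusted p 0.05 in limma with Benjamini-Hochberg adjustment, and p values of single measures are from exact permutation tests. A sample had a median of 970 of 4441 probes above background, and differences of probes below it rest on background-level signal. Against its alternatives, the probe count stayed within 1.5 times in 13 of 15 for LO against PO, 11 of 14 for A+LO against A+PO, 10 of 13 for the averaged oils, 10 of 16 for A+PO against PO, 0 of 16 for A+LO against LO and 2 of 14 for the interaction. For sets this was 17 of 17, 10 of 16, 11 of 15, 13 of 18, 8 of 18 and 4 of 16. Composition kept its side of the threshold and its direction in 13 of 13, 12 of 13 and 8 of 13 (LO against PO, A+LO against A+PO, interaction), detected probes in 4 of 5, 2 of 4 and 4 of 4, and the Shannon index in 10 of 12, 7 of 12 and 8 of 12. Both median scalings leave the Shannon index unchanged by construction, so they are counted as kept without testing it.

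With the background-subtracted signal, A+LO against LO had 425 probes (32 higher, 393 lower) and 29 sets, and the interaction 52 probes, 1 set (b6948) and a pseudo-F of 2.13 (p 0.0541). The Shannon differences were -0.513 (p 0.0455) for A+LO against A+PO and -0.314 (p 0.0455) for the interaction. With the processed signal, A+LO against LO had 383 probes (23 higher, 360 lower) and 30 sets, and the interaction 0 probes and 0 sets (99 and 5 at an unadjusted p under 0.05) and a pseudo-F of 1.37 (p 0.177). Set counts were 1 (b6962) for A+LO against A+PO and 2 (b6962 and b7009) for the averaged oils, all lower.

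With quantile scaling over all samples, A+LO against A+PO and the averaged oils had 1 probe each (b6965_3_2). A+PO against PO reversed to 12 probes (9 higher, 3 lower) and had 15 sets (2 higher, 13 lower), and A+LO against LO had 89 probes (23 higher, 66 lower) and 23 sets (1 higher, 22 lower). The interaction reversed to 1 lower probe (b6963_2_1) and 1 lower set (b6963), with a pseudo-F of 1.05 (p 0.271). Shannon differences reversed to 0.00825 (p 0.387) for LO against PO and 0.00263 (p 0.791) for A+LO against A+PO. Within each dye, they reversed to 0.00916 (p 0.385) and 0.00281 (p 0.590), and the interaction had -0.00662 (p 0.0498), 1 probe (b6955_1_8), 0 sets (2 at an unadjusted p under 0.05) and a pseudo-F of 1.04 (p 0.325). A+LO against LO then had 762 probes (28 higher, 734 lower) and 51 sets. Quantile scaling makes the value distributions alike, which by construction takes most of the Shannon difference away.

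With the median of all probes, A+PO against PO had 299 probes (38 higher, 261 lower) and 19 sets, A+LO against LO 665 probes and 46 sets, all lower, and the interaction reversed to 178 probes (1 higher, 177 lower) and 12 sets. A+LO against A+PO had 30 sets and the averaged oils 7, all lower, and composition in A+LO against A+PO gave 3.12 (p 0.00408). With loess, each oil comparison had 1 probe (b6965_3_2), and A+LO against A+PO and the averaged oils 1 lower set each (b6962). A+PO against PO had 81 probes (14 higher, 67 lower) and 26 sets, A+LO against LO 215 probes (49 higher, 166 lower) and 30 sets, and the interaction reversed to 1 lower probe (b6952_5_13), with 1 higher set (b6948). Shannon differences were -0.273 (p 0.0390) for A+LO against A+PO and -0.266 (p 0.00649) for the interaction. With the median of kept probes, LO against PO and the averaged oils had 1 probe each (b6965_3_2), A+PO against PO reversed to 317 probes (316 higher) and 16 sets, and A+LO against LO reversed to 485 probes (480 higher), with 46 sets. A+LO against A+PO had 23 sets, the averaged oils 5 (b6945, b6948, b6968, b6996 and b7005), all higher, and the interaction 0 probes and 0 sets (261 and 11 at an unadjusted p under 0.05).

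Without a filter on dim probes, A+LO against A+PO had 3132 probes (3102 higher, 30 lower) and 47 sets, A+LO against LO 5 probes (b6965_4_9, b6973_5_4, b6983_1_18, b6984_5_2 and b6989_5_3) and the interaction 3724 probes (3723 higher) and 63 sets. The mean over all probes of a set gave the same 47 and 63. With probes above background in every sample of a group, A+PO against PO had 418 probes, A+LO against LO 118 (24 higher, 94 lower) and 5 sets (b6985 higher; b6942, b6973, b6984 and b6987 lower), and the interaction 5 probes (all of set b7008), 0 sets (11 at an unadjusted p under 0.05), a pseudo-F of 2.15 (p 0.0541) and a Shannon difference of -0.314 (p 0.0346). With outlying spots kept, A+LO against LO had 360 probes (81 higher, 279 lower) and 1 set (b6995), the interaction 658 probes and 53 sets, and the Shannon difference of A+LO against A+PO was -0.435 (p 0.0478). Detection at 3 background SD reversed LO against PO to 168.8 probes (p 0.764). It was not run for the other comparisons, since the background SD of the 4 A+LO samples with unsettled numbers was not used.

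Without an array block, A+PO against PO had 0 probes and 0 sets (209 and 19 at an unadjusted p under 0.05), A+LO against LO 0 probes (38) and the interaction 0 probes and 0 sets (16 and 1). A+LO against LO had 11 probes with a fixed array block and 0 with the compared groups alone (116 at an unadjusted p under 0.05). With the replicate block, A+LO against LO had 0 probes over the 2 shared numbers that are settled (17 at an unadjusted p under 0.05), where the samples share only a number. No paired analysis was possible for A+LO against A+PO because the numbers of 4 A+LO samples are unsettled, which leaves 1 settled number shared. A slide block was not run, since it is confounded with the oils and moves nothing within a slide, and the preset family lists were not run. The compared groups alone gave no separate value for the averaged oils and the interaction.

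Without the array of PO 1 and A+PO 1, A+LO against LO had 14 probes, the interaction 213, and A+LO against A+PO a difference of -182 detected probes (p 0.0833). Without the array of LO 4, A+LO against LO had 505 probes (41 higher, 464 lower) and 28 sets, and A+LO against A+PO -224.5 detected probes (p 0.0779). Leaving out single samples, the interaction ran from 0 probes (without PO 1; 355 at an unadjusted p under 0.05) to 371, with 66 without A+LO 1, 189 without A+PO 4 and 206 without A+PO 6. Its sets ran from 0 (without PO 1 or A+LO 1; 28 and 25 at an unadjusted p under 0.05) to 39, with 18 without PO 4 and 16, 19 and 15 without A+PO 4, 5 and 6. A+LO against LO ran from 4 probes (without LO 6, 8, 9 or 11, or the A+LO sample on LO 6's array) to 504 (LO 4; 38 higher, 466 lower), with no higher probe in 7 of the 13 refits (without LO 3, 6, 8, 9 or 11, A+LO 9, or the A+LO sample on LO 6's array), and 12 probes without LO 3, 105, 6 and 20 without A+LO 1, 9 and 11, and 487, 6 and 11 without the A+LO samples on the arrays of LO 4, 8 and 9. Its sets ran from 0 (2 at an unadjusted p under 0.05 with all samples) to 27 (LO 4), with 24 without LO 4's partner. Detected probes ran from -326 to -182 for A+LO against A+PO, with p above 0.05 without A+PO 1, 2 or 3, A+LO 9 or 11, or the A+LO samples on the arrays of LO 4 and 6 (p from 0.0519 to 0.0833), and from -119.7 to -72.7 for the interaction (p 0.0563 without the array of LO 11). The Shannon difference ran from -0.553 to -0.277 for A+LO against A+PO and from -0.365 to -0.195 for the interaction.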
